A study of Homo sapiens with 3 samples.

How the data were processed

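Chromatin from C4-2B cells was crosslinked with disuccinimidyl glutarate (2 mM, 45 minutes) and then with formaldehyde (1%, 10 minutes), sonicated, and immunoprecipitated with an antibody to NRP2, per the labels' protocols. Libraries were started from 10 ng of DNA, amplified for 13 cycles and size-selected at 250 to 450 bp. The 2 NRP2 libraries and the 1 input library were grouped by the antibody named in the labels. The labels do not say whether the NRP2 libraries came from separate cultures. The submitters' processing notes name bcl2fastq 2.17, Trimmomatic 0.33, Bowtie2 2.2.3, Picard and deepTools, and the build hg38, with no role or order. The region caller, its windows and its normalization are not given in the sources used here. The titles carry the tag 45M, whose meaning is not stated, and the depth behind each value is otherwise unknown, so no interval that needs a read count was computed.

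The 2 deposited lists hold a chromosome, start, end and 1 signal value per region. Both lists are named by the authors as comparisons of input with NRP2. The track title of list A names input and NRP2 and that of list B NRP2 alone, while the longer name of list B reads as differing peaks of input against a pair of libraries, whose tags no label explains. The names of both carry a tag that reads as a p-value threshold of 0.05. The deposited signal is not normalized to width or depth as far as the values show. Every value of list A was a whole multiple of 1/3, within 1e-05 after multiplying by 3, and every value of list B a whole multiple of 1/2, as means of whole counts over 3 and 2 libraries would be. For list B, such a mean would go with the pair of libraries in its name. The series holds 3 libraries, so a mean over 3 of them would include the input and share libraries with a mean over 2. Which libraries were averaged in either list is not stated outright, so list A values may be in part input signal. All regions lay on a 50-bp grid, no region overlapped another of its list, and both lists covered 24 chromosomes. Alignment choices made before deposit can act on repeats, since a read that matches several copies is placed by the aligner. The effect of trimming, of any duplicate removal and of alignment on the regions was not tested. A list of regions that passed a threshold holds no value for other places, so the lack of a region is not a measured 0.

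Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Gene spans came from a RefSeq table for GRCh38.p14, the same build as hg38, with 59679 genes on the 24 chromosomes, of which 20037 are protein-coding. The table has no strand and no exons. The planned promoter, UTR, exon and intron classes were therefore replaced by protein-coding gene, other annotated gene alone and outside genes. Distance to a start was replaced by distance to either gene end, within 1000, 10000 and 100000 bp, and the gene window reached 5000 bp on both sides of a gene in place of 5000 bp upstream. The planned tests of G+C content and of motifs, which need the genome sequence, were not run. Coordinates are printed 1-based.

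Overlap meant at least 1 bp, and was compared with 1000 shuffles of list B within chromosomes, with a one-sided permutation test. List A was kept in place in all overlap shuffles. Region classes were compared with 1000 shuffles by a two-sided permutation test, with Benjamini-Hochberg adjustment over the classes and lists (12 tests). For gene lists, the number of members with a region was set against 10000 random lists of protein-coding genes on the autosomes and X, matched on gene length in 10 bins of equal size, by a two-sided permutation test with Benjamini-Hochberg adjustment over 13 gene lists and 2 region lists (26 tests), at a threshold of 0.05. The smallest p these lists allow is 0.0002. Of 384 gene list entries, 381 matched the annotation, and LOR, PCA3 and SCHLAP1 did not. No single gene was tested.

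The designs, gene lists and first alternatives were fixed before the data were examined. The genes named are, by a rule fixed then, the 10 protein-coding genes on the autosomes and X with the highest region value in each list, 11 genes fixed by name, and examples from up to 4 members per gene list with the highest values; some of these genes are not reported here. Alternatives fixed then were the stronger 50% of each list by value, regions closer than 1000 bp merged, chromosomes 1 to 22 and X alone, a reciprocal overlap of 50%, overlap within 1000 bp, gene ends within 3000 bp, ends of protein-coding genes alone, genes with a region within 1000 bp of an end, the nearest gene, and Fisher's exact test with no length matching. Alternatives chosen after seeing the data were shuffles within 1-Mb bins, shuffles over occupied 100-kb bins, rotation of each chromosome, regions overlapping the other list, the lists without 1-Mb bins of at least 3 times the list B median, and matching of genes also on protein-coding genes within 500 kb or on regions within 1 Mb. Alternatives used 200 shuffles, except those within 1-Mb bins, which used 1000.

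The overlap test, the gene list test and the share of list A in protein-coding genes were tested on simulated data; the other counts were not. With 155463 simulated list B regions, planted overlaps of 0, 10 and 30% were recovered as 0, 10 and 30%. With 104438 list A regions, a planted shift of 10% of regions into protein-coding genes was recovered as 10%. For the gene list test, the regions of each list were first placed at random within chromosomes. Among 200 random lists of 40 genes out of 19974, 2.5% were then called at p under 0.05 in list A and 4% in list B. When up to 10 further members of each were given a region, 95.5% and 98% were called. Neither the crowding of the deposited regions nor gene lists gathered at a few loci were simulated, so these rates need not hold there.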

Results

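Neuropilin-2 (NRP2) is a cell-surface co-receptor for semaphorins and vascular endothelial growth factors, and the title of the series places it in the control of androgen-driven transcription in advanced prostate cancer. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) recovers DNA crosslinked to a protein and compares it with input, the same chromatin without the antibody step. Here it was applied to C4-2B, a human prostate adenocarcinoma line. The series holds 2 NRP2 ChIP libraries, made with the antibody clone C9, and 1 input library. The values analysed were 2 deposited lists of regions on hg38, each region with 1 value, named list A and list B below. No value per library was analysed here, so no region had a replicate error, and the read depth behind a value was unknown. Neither list carries a sign, and whether ChIP lay above or below input in a given region is not given in the sources used here.

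The question behind the series is where NRP2 occupied chromatin in these cells. List A held 104438 regions over 38041.9 kb, and list B held 155463 regions over 55937.6 kb. The median region was 300 bp wide in both lists, with an interquartile range of 250 to 400 bp. The median value was 34.3 in list A, with a range of 12 to 16638, and 35.5 in list B, with a range of 8 to 17594.5. The value grew with region width, with a Spearman rho across regions of 0.82 in each list, and regions are not independent replicates. Values are the authors' own, may include input signal, and are used here only to rank or describe regions within a list.

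Among protein-coding genes, the highest values of list A lay at the subtelomeric double homeobox gene DUX4, the splicing factor gene RBFOX1, RILPL1, RPH3AL, the glutamate receptor gene GRM4, KLHDC4, CCDC187, the microtubule-binding protein gene CLASP1 and the predicted genes LOC124905450 and LOC124900476. In list B they lay at FAM120B, the corepressor gene TLE4, DOCK1, ENOX2, MICAL3, ADAP1, LOC102724250 and, shared with list A, DUX4, LOC124905450 and LOC124900476. The list A regions of LOC124905450, LOC124900476 and CCDC187 lay beside the gene, 2324, 2246 and 450 bp away. The first of these overlapped the pseudogene ROCK1P1. In list B, the regions of LOC124905450 and LOC124900476 lay 4024 and 2246 bp away. The DUX4 region of list A spanned chromosome 4, 190176601 to 190180300, with a value of 1785, and overlapped a list B region with a value of 1524. In RBFOX1 the highest region of list A, at chromosome 16, 6371951 to 6373750, had a value of 1408, and the gene held 154 list A and 204 list B regions along its 2473620 bp. The highest region of RILPL1 lay inside the gene span at chromosome 12, 123510351 to 123513350, with a value of 1462 in list A against 286.5 for the overlapping region in list B. The highest region of FAM120B, at chromosome 6, 170398251 to 170400450, had a value of 2389 in list B and overlapped a list A region with a value of 769.7. In CLASP1 both lists held the same interval, chromosome 2, 121610051 to 121612600, with a value of 788 in list A and 639.5 in list B. TLE4 held 119 list B regions and 5 list A regions, and its highest list B region, at chromosome 9, 79634601 to 79641800, overlapped no list A region. It lies between 79 and 80 Mb, where list B held 548 regions against a median of 28 per 1-Mb bin. DOCK1 and ENOX2 also lie in stretches crowded with list B regions, at 4.07 and 7.82 times the list B median. The list A counts of these 2 stretches were 1.87 and 0.933 times the list A median. LOC102724250 was the other gene whose highest list B region, at chromosome 1, 629001 to 631450, overlapped no list A region. The gene spans carry no exon limits in the annotation used here, so no region was assigned to an exon or intron. These genes do not hold most of the highest values of the lists. Of the 30 highest regions of each list, 0 in list A and 1 in list B had a protein-coding gene within 5000 bp as the nearest annotated gene. Whether reads that match several copies of a sequence raise the values at the genes named here was not tested.

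The overlap of the lists asks how far the 2 sets of calls name the same places. In list A, 46000 regions, or 44.0%, overlapped a list B region by at least 1 bp. The share was 3.62% ± 0.057 (SD over 1000 shuffles) when list B positions were shuffled within chromosomes, a ratio of 12.2. In list B, 45496 regions, or 29.3%, overlapped list A, against 2.46% ± 0.038 (SD over 1000 shuffles), a ratio of 11.9. No shuffle reached either observed share (one-sided permutation p = 0.001, the smallest that 1000 shuffles can give; lower-tail p = 1). Overlapping regions had higher median values than the rest, at 41.7 against 30.3 in list A and 49 against 31.5 in list B. Values grow with width, and a wider region meets the other list more easily. The higher medians may therefore come in part from width, which was not adjusted for. Across the 44477 list B regions that overlapped a single list A region, paired with that region, Spearman's rho was 0.54 for the values and 0.37 for values per 200 bp of region. The name of list B points to input and a pair of libraries that the labels do not identify, and the libraries behind list A are not given in the sources used here. Means over 3 and 2 libraries of this series would share libraries. Lists that share libraries overlap for that reason also, so the overlap is not independent replication. The ratio fell to 8.34 for list A and 7.85 for list B when each list B region was moved only within its own 1-Mb bin, with p = 0.001 by the same permutation test.

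**Figure D1:**
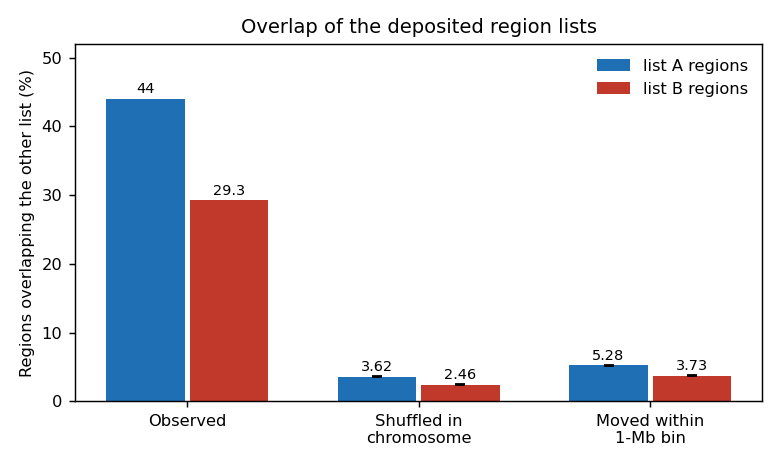
Share of regions, in percent, that overlapped the other list by at least 1 bp, for list A and list B. Bars show the lists as deposited, after shuffling list B within chromosomes and after moving each list B region within its own 1-Mb bin. List A was kept in place throughout, and error bars are the SD over 1000 shuffles. The observed 44.0% of list A and 29.3% of list B stand above the shuffled shares of 3.62% and 2.46%.

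The androgen-regulated genes answer the question most directly tied to the title of the series. At KLK3, which encodes prostate-specific antigen (chromosome 19, 50854915 to 50860764), list A held 2 regions and list B held 0. The higher of these lay inside the gene span at 50857551 to 50858000, with a value of 88. At its neighbour KLK2 (50873439 to 50880567) list A held 3 regions and list B held 1, and the regions at 50871151, which lie 2039 bp from the gene in list B, overlapped between the lists, with values of 63.3 and 26.5. At TMPRSS2 (chromosome 21, 41464305 to 41508158), an androgen-induced serine protease gene, list A held 3 regions and list B held 4. Those of the lists overlapped at 41469551 to 41469800 in list A, with a value of 38 there and 86 in list B, and again at 41493951, with values of 20.3 and 35. FKBP5, a steroid receptor co-chaperone gene on chromosome 6, held 1 list A region at 35657551 to 35657750, with a value of 22.7, and 0 in list B.

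NRP2 itself (chromosome 2, 205682501 to 205798131) held 2 list A regions inside its span, with values of 56.3 at 205689651 and 51.3 at 205775401, and 0 in list B. Its relative NRP1 held 1 list A region, with a value of 18, and 0 in list B. FOXA1, a pioneer transcription factor gene, held no region in either list. HOXB13, a prostate transcription factor gene, held 0 in list A and 2 in list B, the higher at chromosome 17, 48733651 to 48734150, with a value of 84 and 4901 bp from the gene. That region overlapped a list A region that lies just beyond the gene window, while the other, at 48728851 to 48729150 with a value of 29.5, overlapped none. UBE2C, a ubiquitin-conjugating enzyme gene of mitosis, held 1 list A region across a gene end, with a value of 13.7, and 0 in list B.

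**Figure D2:**
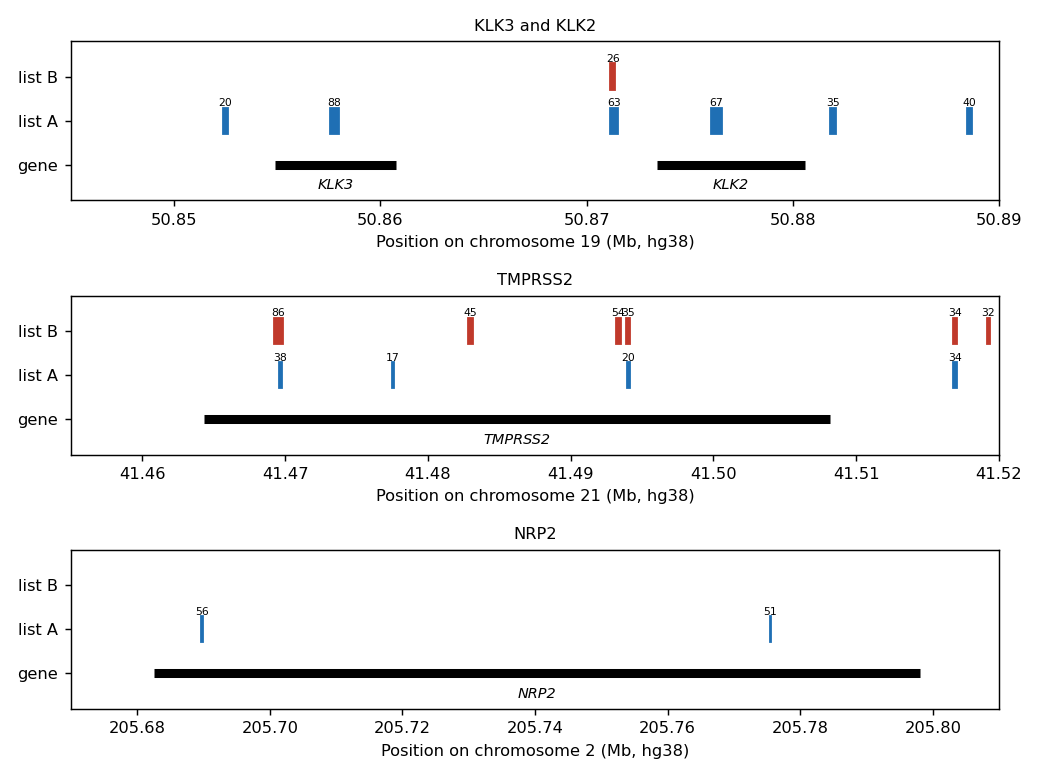
Maps of the regions around KLK3 and KLK2, TMPRSS2 and NRP2, with positions in Mb on hg38; boxes are regions of list A and list B drawn to scale, the number above each is its rounded value, and black bars are gene spans. KLK3 and NRP2 each held 2 list A regions and 0 list B regions, and TMPRSS2 held 3 and 4.

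Of the 40 androgen-response genes, 25 held a list A region against 26.8 in length-matched random lists (permutation p = 0.5997, adjusted p = 1). In list B, 21 held a region against 24.9 (permutation p = 0.2168, adjusted p = 0.7045). Within 1000 bp of a gene end the ratios to random lists moved from 0.932 to 1.99 in list A and from 0.844 to 0.312 in list B, and neither passed the test. In 15 of the 40 the lists held overlapping regions, against 15.9 in length-matched random lists for list A and 15.8 for list B (permutation p = 0.8797 and 0.9093). An example is MAF, a leucine zipper transcription factor gene, with values of 199 in list A and 226.5 in list B at chromosome 16, 79391901. Others are the prostaglandin receptor gene PTGER4, with 138 and 114.5, and ABHD2, with 87.7 and 96.5. The annotated spans of MAF and PTGER4 were 398116 and 66886 bp long. Without exon limits, how far these regions lie from the coding parts is unknown. In a list of 24 transcription factor and cofactor genes of androgen signalling, 19 held a list A region against 18.9 at random and 18 a list B region against 17.8, with permutation p = 1 for both. Among these, the ETS factor gene ERG held 41 list A and 73 list B regions, and lies in a stretch of chromosome 21, 37000001 to 43000000, where the list B count was 7.61 times its median and the list A count 4.13 times; TMPRSS2 lies in it too. The corepressor gene NCOR1 had overlapping regions at chromosome 17, 16144651, with values of 86 and 99.

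Counted gene by gene, fewer of the replication-dependent histone genes held a region than of length-matched genes, in both lists. List A had 0 of 44 against 11.01 at random (central 95% of random lists 6 to 17), and list B had 2 of 44 against 12.5 (7 to 19), with a permutation p of 0.0002 and 0.0004 and an adjusted p of 0.0052 for both. The 2 in list B, H1-3 and H4C6, share a single region beside them at chromosome 6, 26235451 to 26235650, with a value of 20. The 44 genes lie at 3 loci on chromosome 6, so they are not independent draws and these p-values are too small. With the loci as units, all regions over the whole loci were counted, also those between genes, against random windows of equal length. By that measure list A had 7 regions and did not pass (central 95% 7 to 28, permutation p = 0.0732). List B had 3 (6 to 42, permutation p = 0.0104). The 7 in list A lay outside the 5000-bp windows of the 44 genes, so the tests differ in measure as well as in unit. Whether the shortage at the genes themselves holds with loci as units was not tested. Fewer ribosomal protein and translation genes also held a list B region, 2 of 38 against 11.3 (6 to 17; permutation p = 0.0006, adjusted p = 0.0052), and these were RPL4 and RPL38, with values of 36 and 16. In list A, 6 of 38 held one against 11.03 (permutation p = 0.0864, adjusted p = 0.4492), among them RPS6 with a value of 39.3 and RPS14 with 38.7. Both list B calls ended without the 1-Mb bins of at least 3 times the list B median (permutation test, adjusted p = 0.0842 for each). All 3 calls ended in permutation tests on regions that overlap the other list (adjusted p = 0.0676). There, histone genes in list A and list B and translation genes in list B stood at 0, against 5.29, 5.33 and 4.96 at random. They also ended for regions within 1000 bp of a gene end (permutation test, adjusted p = 0.9736), at 0, 1 and 0 against 3.19, 4.05 and 3.08. Few members were expected in both settings. The translation call also ended by nearest gene (permutation test, adjusted p = 0.5026) and in the stronger 50% of regions (permutation test, adjusted p = 0.1681).

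The other lists did not pass the test. Of the 24 neuroendocrine genes, 17 held a list A region against 11.6 (permutation p = 0.02, adjusted p = 0.13) and 12 a list B region against 11.2 (permutation p = 0.8805). The neuronal splicing factor gene SRRM4 had a highest value of 163 in list A and 166.5 in list B, and the RNA-binding protein gene ELAVL3 had overlapping regions at chromosome 19, 11464701 to 11465300, with values of 110 and 101. In the neuropilin, VEGF and semaphorin list, 19 of 27 held a list A region against 19.8 and 17 a list B region against 18.5. SEMA3F, a semaphorin gene whose product binds neuropilin-2, had the same interval in both lists 858 bp outside the gene, at chromosome 3, 50153751 to 50154200, with values of 137 and 128.5, and the semaphorin receptor gene PLXNA2 had 135 and 73.5 at chromosome 1, 208215251. Nuclear pore and lamina genes gave 24 of 39 in each list, against 27.3 and 25.1. The pore protein gene RANBP2 had the same interval in both, chromosome 2, 109199301 to 109200000, with values of 488 and 361.5. The annotation used here gives RANBP2 a span of 1122820 bp, 108719482 to 109842301, without exon limits. How far this interval lies from the coding part of the gene is therefore unknown, and it may belong to another gene. NUP153 had overlapping regions at chromosome 6, 17618851, with values of 105 and 62.

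Mitotic cell cycle genes held a region in 13 of 26 for list A, against 13.6, and in 12 for list B, against 12.8. MKI67 had a highest value of 40.3 in list A and 68 in list B, at regions that did not overlap, though other regions of the lists did overlap at this gene. DNA damage response genes gave 17 of 24 against 17.8 and 16 against 16.4, with BRCA1 at 63 and 70.5 in overlapping regions. Autophagy and endocytosis genes gave 11 of 20 against 13.2 and 13 against 12.3, with ATG5 at 57 in each list, in regions at different places. The highest ATG5 region of list B overlapped another list A region. Markers of stromal, endothelial and immune cells gave 20 of 28 against 16.5 and 19 against 15.5, with the cadherin gene CDH5 at 156 and 108.5 in separate regions. Each of these CDH5 regions overlapped another region of the other list. Genes of other tissues gave 13 of 29 against 12.4 and 14 against 12.1, with the muscle myosin gene MYH7 at 103 and 45.5. Basal and luminal epithelial genes gave 7 of 18 against 9.20 and 9 against 8.70, with GOLM1 at 262 and 195. The adjusted p of these 6 lists and of the neuropilin and nuclear pore lists lay between 0.7045 and 1 in the 26 tests. Of 19974 protein-coding genes on the autosomes and X, 11149 (55.8%) held a list A region, 10549 (52.8%) a list B region, and 6431 (32.2%) regions that overlapped between the lists.

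**Figure D3:**
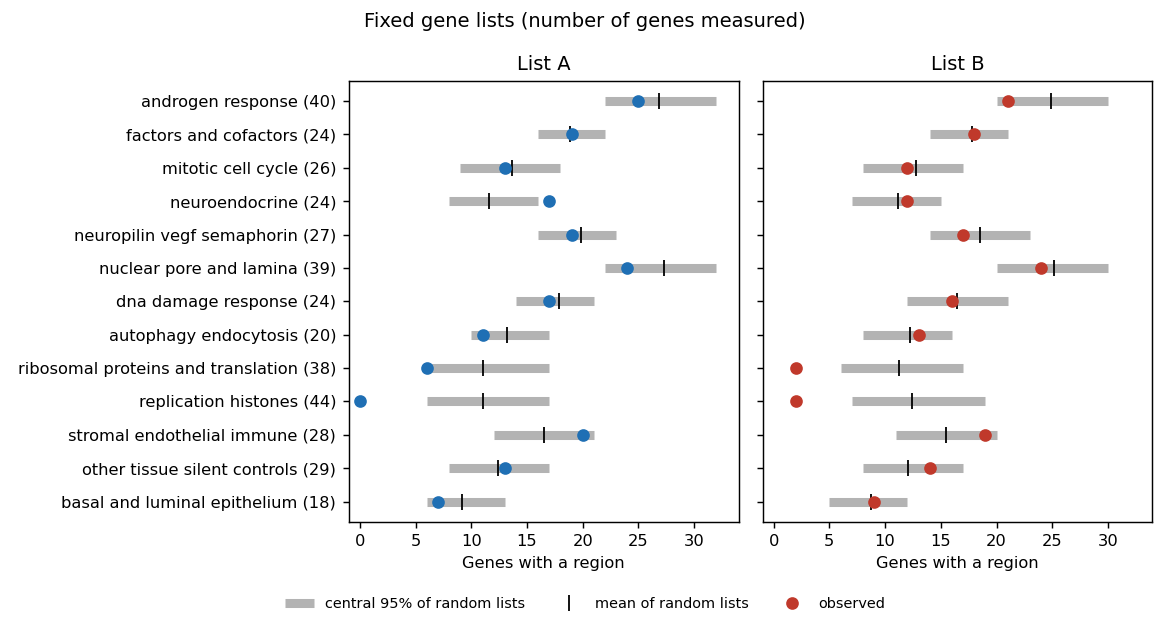
Number of genes with a region within the gene span or 5000 bp on either side, for the 13 gene lists (number of genes in parentheses) in list A and list B; points are observed counts, ticks the mean and grey bars the central 95% of 10000 random lists matched on gene length. Replication histones lie below the bar in both panels, with 0 of 44 and 2 of 44.

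Regions lay less often in protein-coding genes and near gene ends than shuffled positions did. In list A, 36.7% of midpoints lay in a protein-coding gene against 41.4% ± 0.151 (SD over 1000 shuffles), a ratio of 0.887, and in list B 33.5% against 39.8% ± 0.121, a ratio of 0.841. Within 1000 bp of either end of a gene, list A had 4.17% against 6.19% ± 0.076, a ratio of 0.674, and list B 3.90% against 6.02% ± 0.060, a ratio of 0.647. Within 10000 bp the ratios were 0.926 and 0.884. Regions outside annotated genes made up 48.3% of list A against 45.0% and 52.1% of list B against 47.6%, and those in another annotated gene alone made up 14.98% against 13.6% and 14.4% against 12.6%. Each difference had an adjusted p of 0.002 (two-sided permutation test, the smallest that 1000 shuffles can give). The shuffles placed each region on its own, while list B regions crowd into stretches. The SD and p therefore describe independent placement and may be too small. The share within 100000 bp of a gene end lay slightly above shuffled positions, at ratios of 1.03 and 1.02, and turned below them when the ends of protein-coding genes alone were used, at 0.967 and 0.909. With each region moved within its own 1-Mb bin, that share had ratios of 1.001 in list A (permutation test, adjusted p = 0.2118) and 0.998 in list B. In the same setting the ratio in another annotated gene alone fell to 1.04 in both lists, and those in protein-coding genes were 0.906 and 0.899. Shuffled positions could fall in assembly gaps; limited to 100-kb bins that hold a region or an annotated gene, the ratios were 0.845 and 0.797 in protein-coding genes, 0.636 and 0.609 within 1000 bp of a gene end, and 0.977 and 0.965 within 100000 bp.

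List B regions were unevenly spread over chromosomes, and list A regions less so. Chromosome X held 164 list B regions per Mb against 50.4 over all chromosomes, while list A held 26.6 per Mb there against 33.8 over all. Chromosome 18 held 96.7 list B and 29.8 list A regions per Mb, chromosome 13 held 76.5 and 21.4, and chromosome 21 held 137 and 71.9. On chromosome 2 the order was the other way, with 16.9 list B and 28.0 list A regions per Mb. The stretch of chromosome 13 from 61000001 to 70000000 had 20.1 times the median list B count per 1-Mb bin and 0.5 times the list A median. The stretch of chromosome 18 from 18000001 to 41000000 had 9.89 and 1.87 times, and those of chromosome X from 62000001 to 89000000 and from 90000001 to 156000000 had 7.07 and 1.07 times and 7.82 and 0.933 times. In all, 501 of 3101 bins (16.2%) held at least 3 times the list B median of 28 regions, and they contained 81933 list B regions (52.7%) and 27439 list A regions (26.3%). These counts are a description with no test, and the multiple of 3 was set after the counts had been seen.

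**Figure D4:**
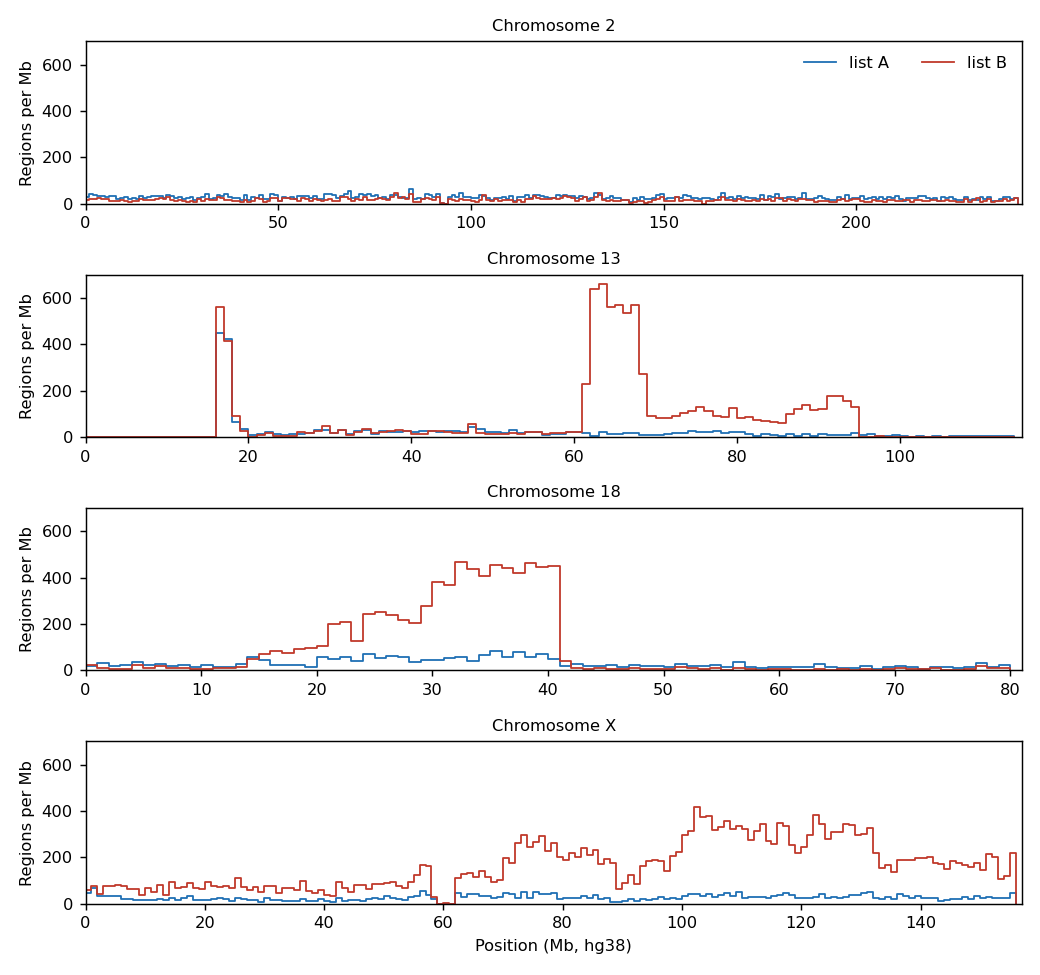
Number of list A and list B regions per 1-Mb bin along chromosomes 2, 13, 18 and X, with positions in Mb on hg38. List B steps up in stretches of chromosomes 13, 18 and X, to 20.1 times its median between 61000001 and 70000000 on chromosome 13, where list A lies at 0.5 times its own.

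The highest values of both lists lay on chromosome 21 beside the ribosomal DNA units, whose 45S genes encode the ribosomal RNA precursor. The units were chosen after the values had been seen. Past the end of RNA45SN3 (8389035 to 8402343), list A had its highest region, 8408901 to 8421300, with a value of 16638. Past RNA45SN2 (8205988 to 8219302), list B had its highest, 8225951 to 8238200, with a value of 17594.5. Over the 26 kb past each 45S gene, called regions had 171 to 206 per 200 bp in the 3 units and 2 lists, and inside the 45S genes 41.7 to 47.9. Called regions covered 81.3 to 92.1% of the former and 30.1 to 36.4% of the latter. Reads from near-identical repeat units cannot be assigned to a single unit, so the values of single units are uncertain.

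**Figure D5:**
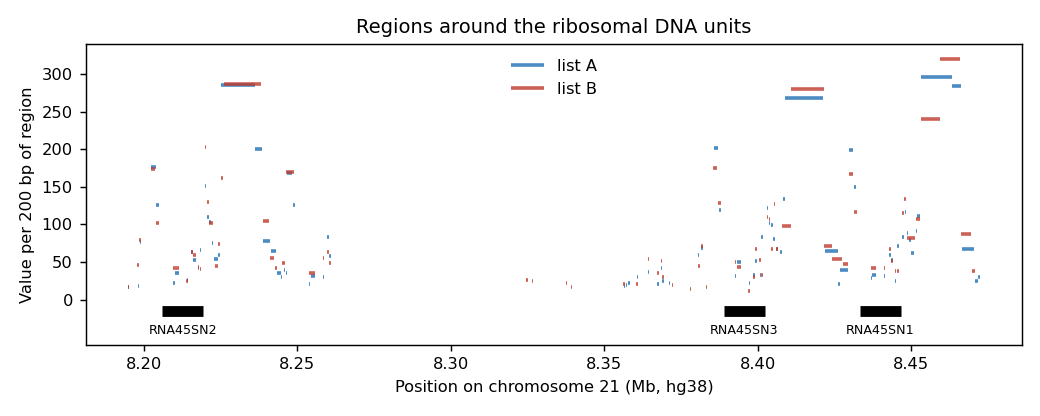
Value per 200 bp of each list A and list B region around the ribosomal DNA units of chromosome 21, with positions in Mb on hg38; black bars are the 45S genes RNA45SN2, RNA45SN3 and RNA45SN1. The highest list A region past RNA45SN3 has a value of 268 per 200 bp, and the highest regions lie beside the bars and not on them.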

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

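Of 326 values under an alternative setting, 290 were counted as kept. For overlap and region classes, kept meant the same direction and side of the threshold, and for counts within 1.5 times. A gene list that passed under neither setting counted as kept whatever its direction. Gene list values made up 224 of the 326, and 205 of these were kept. Ratios per chromosome were held to the stricter bound of their 95% binomial interval, and none of the 6 stayed within it. The overlap ratio stayed above 1 under all 7 alternatives, at 4.10 to 35.2 in list A and 4.48 to 34.9 in list B, and the ratio within 1000 bp of a gene end stayed at 0.515 to 0.679 and 0.421 to 0.682 (within 3000 bp, 0.791 and 0.750). The androgen-response list passed no test under any of its 9 settings (lowest adjusted p 0.6199 in list A and 0.2825 in list B), though within 1000 bp of a gene end its ratio moved from 0.932 to 1.99 in list A (6 genes against 3.01) and from 0.844 to 0.312 in list B (1 against 3.203). Settings marked here as added were chosen after seeing the data. The stronger 50% of each list by value has by construction fewer regions, 52219 in list A and 77731 in list B, as do, added, regions overlapping the other list (46000 and 45496) and list B without its bins of at least 3 times the median (73530). In the stronger 50%, regions per Mb relative to all chromosomes were 0.712, 0.573 and 2.44 on chromosomes X, 13 and 21 in list A, and 3.58, 1.73 and 3.13 in list B. The ratio within 100000 bp of a gene end reversed with ends of protein-coding genes alone (0.967 in list A, 0.909 in list B), in occupied bins (added, 0.977 and 0.965) and, in list B, within 1-Mb bins (added, 0.998), where the list A call ended (1.001, permutation test, adjusted p = 0.2118). The cause was not tested.

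With genes counted within 1000 bp of an end, no list passed (0 in list A, 0 in list B): the histone ratios were 0 and 0.247, and the list B translation ratio was 0 (permutation test, adjusted p = 0.9736), where at most 4.05 members were expected. With overlapping regions alone (added), histone ratios were 0 in both lists and the list B translation ratio 0 (permutation test, adjusted p = 0.0676), and 0 lists passed in either. Without the high bins (added), list B ratios were 0.246 for histones and 0.248 for translation (permutation test, adjusted p = 0.0842), and 0 lists passed in list B. The gene-by-gene list A histone test still passed (0 of 44, permutation test, adjusted p = 0.0052), though its draws are not independent. The number of list A regions over the 3 whole loci, an unlike measure taken with all bins, did not pass (permutation p = 0.0732). The list B translation ratio was 0.618 by nearest gene (adjusted p = 0.5026) and 0.163 in the stronger 50% (adjusted p = 0.1681), both by permutation test, leaving 1 list past the test in each. Without length matching, the list A translation ratio was 0.283 (Fisher's exact test, adjusted p = 3.46e-06) and 2 lists passed in list A. The cause was not tested, beyond the lower counts that each smaller set of regions gives.

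The results on G+C content and motifs, with their alternatives, and regions of matched G+C content as a comparison were not run, since no genome sequence was used here. Ignoring the sign changes nothing, as the values have none. Leaving out a library gave no value. No paired analysis was possible because the lists hold no values per library. Depth is unknown.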

Other observations

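The tests of explanations below were all put in their final form after the results had been seen; those on translation genes and on the histone loci were first worded for both lists together before they were run, and were then split by list. Translation genes in list A, which had not passed the test, stood at 6 within the central 95% of both kinds of matched list (6 to 16) and were left out of the split.

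Besides the ribosomal DNA, the highest values lay near the centromere of chromosome 4 and on chromosome Y. Of the 30 highest regions of list A, 30 overlapped a list B region, with 8 on chromosome 4 and 7 on chromosome 21. The highest away from chromosome 21 were at chromosome 4, 49101001 to 49111750, with a value of 7461, and at chromosome Y, 56827351 to 56838300, with 5465. In list B they were at chromosome Y, 56828501 to 56842000, with 6684.5, and at chromosome 4, 49106901 to 49115800, with 4625. Of the 30 highest regions of list B, 25 overlapped list A, and the other 5 lay between 79 and 80 Mb on chromosome 9, around TLE4. That 1 Mb held 548 list B regions and 47 list A regions.

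List B regions crowded into 24 stretches of at least 5 Mb, each bin of which held at least 3 times the list B median; list A had over 1.2 times its own median in 16 of them and less than its median in 7. Higher copy number in the cells behind both lists was taken to raise both. On chromosome 13, from 61000001 to 70000000, list A had 0.5 times its median, against that reading. Comparison with input could cancel a shared copy gain in 1 list, and the normalization of neither is known. The low list A count therefore does not decide the question there. That stretch has the highest median list B count per bin of the 24 and does not speak for the others. On chromosome 18, from 18000001 to 41000000, list A had 1.87 times its median, so shared copy number stays open there too. A copy-number difference between the libraries that list B compared is a candidate explanation on chromosome 13. Each edge was placed where the list B count of the 1 Mb inside most exceeded that outside, so the contrast at the edges is in part by construction. List B counts per 100 kb stepped from 1 to 48 at 61700001 and from 52 to 16 at 68400000. The 1 Mb inside the lower edge held 31.9 times the regions of the 1 Mb outside (669 against 21), and that inside the upper edge held 538 against 95. List A held 7 inside against 21 outside at the lower edge, and 14 against 9 at the upper. Libraries shared by the lists could carry such a difference into list A as well. Which libraries each list compared is not stated, so the list A counts leave this explanation open. The median list B count per 100 kb inside was 57.5 in bins with a protein-coding gene and 58 in those without. Copy number itself was not measured. The design names no group that bears on this, so no biological explanation was tested.

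Few histone genes held a region in either list, and few translation genes in list B. Gene-dense or region-poor neighbourhoods as the whole cause are argued against for translation genes in list B, where random lists matched on these gave means of 11.3 and 9.26 against the observed 2, below the central 95% both times. For histone genes such lists gave 11.1 and 13.8 in list A and 11.2 and 22.3 in list B against 0 and 2, but they draw genes 1 by 1 while the 44 lie at 3 loci, so both explanations stay open. For the number of regions over the 3 whole histone loci, chance stays open in list A, with 7 against a median of 16 in random windows (7 to 28, permutation p = 0.0732). List B had 3 against 19 (6 to 42, permutation p = 0.0104). That count takes in regions between the genes, so it does not decide on the genes themselves. Base composition, reads shared between near-identical gene copies and any biological explanation were not tested.

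The highest values of both lists lay past the 45S genes of the ribosomal DNA. Many repeat copies read as 1 may account for high values in the units. The spacer had at least 3.57 times the value per 200 bp of the 45S part in the 3 units and both lists, but the spacer was chosen for its high values and the called regions cover unlike shares of both parts, so the ratio leaves this open. Base composition and simple repeats were not tested. No biological explanation was tested.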
